A study of Mus musculus with 24 samples.

How the data were processed

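Transcript levels were measured in the ascending aorta of double knockout mice labelled as male on a high fat diet. Per the labels, 1 arm received no treatment (HFD, called untreated below). The other arm received 5 oral doses of AHC, a scaffold that carries peptides of apolipoprotein B, heat shock protein 60 and Chlamydia pneumoniae. The titles name the treated samples AHC, while the treatment label reads AFC; they were read as 1 treatment. Each arm was sampled at weeks 0, 6, 18 and 30 of the diet, and each of the 8 groups holds 3 arrays. The mice were 8, 14, 26 and 38 weeks old at these times. Age and time on the diet therefore cannot be told apart in any change against week 0. The protocol also names a time point at week 8, which was not analysed here. Whether the 3 arrays of a group come from separate animals is not given in the sources used here, so every p-value measures only the spread between samples.

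The authors hybridised Cy3-labelled RNA to 1-colour Agilent arrays, and the deposited scanner files hold the output of Agilent Feature Extraction 11.5.1.1. The deposited processed signal is an intensity on a linear scale that Feature Extraction background-subtracted and detrended within each array, with no normalization between arrays. Per the file headers, the flags for spots well above background and for outlier spots take 1 of 2 states, here called other values. The deposited series values are the same intensity, rounded, and differ from the scanner files by at most 0.497%. The median raw spot and background intensity, also in the deposited files, was used for 1 alternative. The scanner files hold no mean raw signal, so this alternative used the median in its place.

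Each array has 62976 spots, of which 59305 carry gene probes. Control spots and population outlier spots were left out, and replicate spots of a probe were averaged. The 55681 probes were named through their accessions with RefSeq gene names of the mouse assembly GRCm38.p6, used for names only because the file headers give another build; no coordinates are printed. A name was found for 28331 probes, covering 21368 symbols, and 26469 of the 26732 probes with an NM accession were named. The 27350 unnamed probes entered only an added alternative. Signals were log2-transformed, and the 75th percentile of each array was subtracted. A probe was tested where it lay well above background on all 3 arrays of at least 1 group, which left 36673 probes. Each gene was represented by its tested probe with the highest mean, which gave 16764 genes. No gene spot was saturated. Between 43% and 71.7% of spots lay well above background per array, and the number of arrays limits the precision.

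Linear models were fitted with limma 3.58.1 in R 4.3.3 (files were read with the R package data.table, version 1.17.8). One mean was fitted for each of the 8 groups over all 24 arrays, with 16 residual degrees of freedom and 2.6 prior degrees of freedom. The comparisons were AHC against untreated at each week, the mean of these 4 differences, each later week against week 0 within each arm, and the interaction of treatment with time, as 1 F test and per week. Genes were called at a Benjamini-Hochberg adjusted p under 0.05 over all genes tested. Gene lists were tested with camera, 2-sided, at a preset correlation of 0.01, adjusted over 41 lists (20 of cell types and 21 of pathways). Of the 534 list members, 507 were tested, and 1 older symbol, Ctgf, was matched as Ccn2. Of the camera calls in the 11 comparisons that are no interaction, none held with a correlation estimated per list; camera with an estimated correlation called 0 lists in each of them, and the values stand beside each list. No called list had a median and a test of differing sign.

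These lists, the tests, the filters and the rule for named genes were chosen before the data were examined. The rule takes the 10 genes with the largest rise and the 10 with the largest fall among called genes with an official symbol whose 3 against 3 values did not overlap. For the mean of 4 weeks it asks for the same sign in every week, and for the interaction it takes the largest F. Up to 4 members per called list were added by their adjusted p. Apob and Hspd1 were always included, and some genes that the rule gave are not reported here. Ranking was limited to genes well above background on all arrays of both groups compared. Where a gene was not above background in a whole group, a bound was computed against that group's signal floor and is written "at least". Of the genes the rule gave, those printed are mostly ones whose call held in every fit that left out 1 array. Where a printed call did not, the text says so. Of the called genes the rule gave, many did not hold. For AHC against untreated, 0 of 1, 57 of 99, 21 of 55 and 76 of 85 held at weeks 0, 6, 18 and 30, and 47 of 61 for the mean. Against week 0, 21 of 66, 1 of 22 and 91 of 102 held in untreated aortas at weeks 6, 18 and 30. In AHC aortas 2 of 12, 30 of 79 and 23 of 76 held. Values are log2 differences with the SE of the fit, or means with SD over n = 3 arrays. A list score is the mean of the members on an array, each centred over the 24 arrays.

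Each result was also computed with quantile normalization, with normexp background correction (offset 50) followed by quantile normalization, with the series values, with no filter on dim probes, with a filter at 12 arrays, with the mean of the probes of a gene, with the replicate number or the slide as a block, with array weights, in a fit on only the arrays compared, and after leaving out each array in turn. Alternatives added after the data were seen were fits within slide 1 or slide 2, fits without arrays picked by their sex-linked or pancreatic transcripts, an average of near-identical arrays, all features, and tissue list scores as covariates. Other splits of the arrays were counted for each comparison. On simulated data with the means and residual spread of these arrays, of 100 genes changed 2-fold among 16764, between 10 and 21 were called across the comparisons of 2 groups. Of 100 genes changed 4-fold, between 51 and 66 were called, with 0 to 11 false calls. Lists shifted in simulation were called in 10 of 10 runs, with 0 false lists. The simulated genes were drawn independently of each other, with the same spread in all groups. On these arrays the spread differed between groups, and no list call held with an estimated correlation. The simulation therefore cannot show how often lists or genes were falsely called here. Nor can it give the share of changed genes called where many more genes passed, since the adjusted p depends on that number.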

Results

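Ascending aortas of double knockout mice labelled male were profiled on 24 Agilent arrays, to ask how an oral peptide vaccine (AHC) alters expression while atherosclerosis progresses. The 8 groups were untreated and AHC at weeks 0, 6, 18 and 30 of a high fat diet, with 3 arrays each (n = 3). Of 16764 genes tested, limma called 1 gene between AHC and untreated at week 0, 3297 at week 6, 1984 at week 18 and 7615 at week 30. The direction of the same groups of transcripts differed by week. Contractile smooth muscle transcripts were higher with AHC at week 6, in 11 of 12 members (adjusted p = 0.228 with an estimated correlation). At week 18 the list was called lower with 1 of 12 members past the threshold, a call that ended in 3 of 6 fits that left out 1 array (adjusted p = 0.584 with an estimated correlation). Lymphocyte transcripts were lower with AHC at weeks 6 and 30 and higher at week 18. Sex-linked transcripts and transcripts of heart, skeletal muscle, lung and pancreas also differed between arrays, and at weeks 18 and 30 Ddx3y separated treated from untreated arrays without overlap.

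The arrays lay on 3 slides: replicates 1 and 2 of weeks 0 and 6 on slide 1, replicates 1 and 2 of weeks 18 and 30 on slide 2, and every replicate 3 on slide 3. Untreated arrays were in row 1 and AHC arrays in row 2 of every slide, so row and treatment cannot be told apart. The 75th percentile of the signal ran from 151 to 608. The median SD between arrays of a group was 0.106 in untreated week 30, 0.184 in AHC week 6 and 0.529 in AHC week 18 (log2). In simulated data the fits called 10 of 100 genes changed 2-fold and 51 of 100 changed 4-fold at week 30, so an absent call does not mean no difference. These shares do not carry over to the real week 30 comparison. There 7615 genes passed, which makes the cutoff on the unadjusted p looser than in the simulation.

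Ddx3y, a Y-linked transcript, was well above background on 11 of the 24 arrays, all labelled male. Xist, transcribed from the inactive X of females, was above background on 15 arrays, of which 13 had no Ddx3y. At weeks 6, 18 and 30, Ddx3y was above background on 8 of 9 untreated arrays and 0 of 9 AHC arrays; at week 0 it was on 2 untreated arrays and 1 AHC array. Ddx3y ran from 0.26 to 2.40 where above background and from -6.42 to -4.44 elsewhere (log2 relative to the 75th percentile). Xist was -6.97 to -2.42 on the arrays with Ddx3y and -1.77 to 0.27 on those without. Eif2s3y, also Y-linked, was above background on all 11 arrays with Ddx3y and on 2 others, AHC week 18 replicate 2 and AHC week 30 replicate 1. No Apob probe was well above background on all 3 arrays of any group, so Apob was not tested; 1 of its probes was above background on 2 of 3 untreated week 6 arrays.

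**Figure D1:**
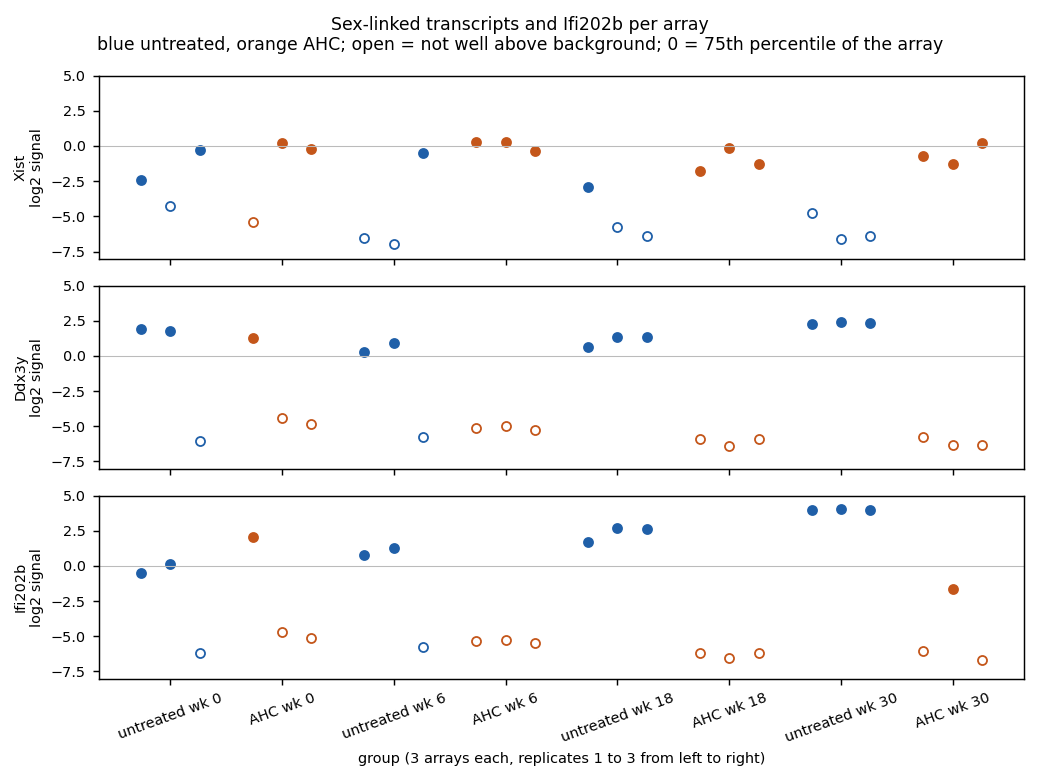
Log2 signal of Xist, Ddx3y and Ifi202b (vertical) on each of the 24 arrays by group (horizontal), with open circles where a transcript was not well above background. At weeks 6, 18 and 30 no AHC array had Ddx3y (0 of 9), against 8 of 9 untreated arrays.

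**Figure D2:**
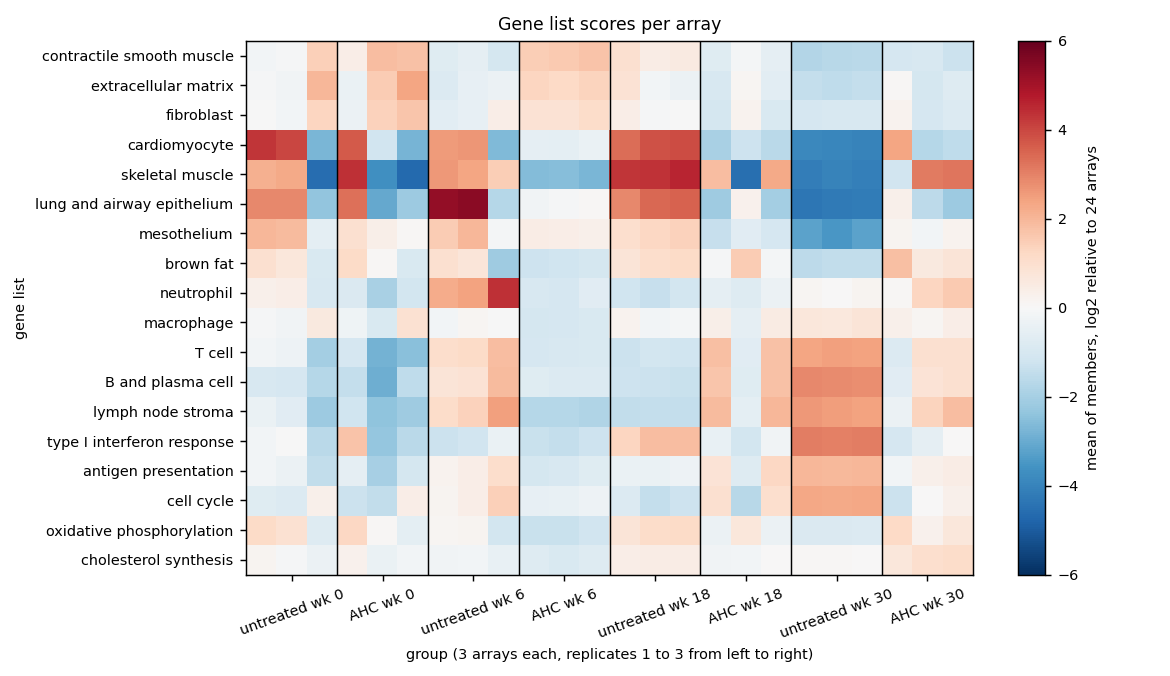
Score of 18 gene lists (vertical) on each array by group (horizontal), in log2 relative to the 24 arrays. The lung list ranged over 9.73, skeletal muscle over 9.2 and cardiomyocyte over 8.27 log2 units, against 3.6 for contractile smooth muscle.

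At week 0, AHC and untreated aortas differed in 1 gene, Prpf19, a subunit of the spliceosome, which rose by 2.55 ± 0.38 (adjusted p = 0.0322, n = 3); it was above background on 2 of 3 untreated arrays. Its call ended without untreated replicate 1 (2.40) or 2 (2.42) and without AHC replicate 1 (2.24) or 2 (2.76). Myh11, the smooth muscle myosin, measured 1.71 ± 0.69 (adjusted p = 0.477) and Cd2 of T cells -2.33 ± 0.80 (adjusted p = 0.439). As lists, contractile smooth muscle had a median of 0.86 (camera adjusted p = 7.58e-05, and adjusted p = 0.706 with an estimated correlation) and T cell transcripts -1.55 (0.0016, and adjusted p = 0.822 with an estimated correlation), with no member past the threshold. limma gave 1625 genes at unadjusted p < 0.05, and values did not overlap in 8.9% of genes, where chance gives 10%. Without untreated replicate 3, which lacked Ddx3y unlike its group, 1473 genes passed; without untreated replicate 1 or 2 or AHC replicate 2 the count was 0, without AHC replicate 1 it was 2, and without AHC replicate 3 it was 5. Week 0 therefore gave no stable list of differences before the diet.

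At week 6, smooth muscle and matrix transcripts were higher and neutrophil and lymphoid transcripts lower in AHC than in untreated aortas. Myh11 rose by 3.96 ± 0.69 (adjusted p = 0.00111), Lmod1, an actin nucleator of smooth muscle, by 3.33 ± 0.46 (0.000305), Tagln by 2.53 ± 0.40 (0.000577) and Dmd, which links actin to the membrane, by 4.41 ± 0.58 (0.000229). Fos rose by 3.17 ± 0.19 (adjusted p = 3.01e-08) and Jun by 2.27 ± 0.25 (6.23e-05), both induced early by stimuli that include tissue handling. The matrix genes Eln and Postn rose by 3.86 ± 0.99 (0.0115) and 2.71 ± 0.66 (0.00864), and Ltbp1 and Tgfb2 of TGF-beta signalling by 3.53 ± 0.50 (0.000305) and 2.88 ± 0.55 (0.00199). Of neutrophil transcripts, S100a8 fell by 4.56 ± 0.67 (0.000375), Retnlg fell by 5.05 ± 0.69 (0.00028) and Camp fell by 4.37 ± 0.67 (0.000488). Of lymphoid tissue, Ccl19 fell by 2.60 ± 0.40 (0.000488), Lck of T cells by 3.12 ± 0.82 (0.0128) and Psmb8 of the immunoproteasome by 2.83 ± 0.69 (0.00892), and Glycam1 of lymph node venules was at least 337-fold lower (0.000475).

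Of the smooth muscle list at week 6, 11 of 12 members rose (median 2.57, camera adjusted p = 6.23e-09, and adjusted p = 0.228 with an estimated correlation), and 11 rose when adjusted over the list alone. Of the extracellular matrix list, 8 of 18 rose (14 adjusted over the list alone, median 1.80, 1.3e-06, and adjusted p = 0.405 with an estimated correlation). Neutrophil members fell in 7 of 10 (9 adjusted over the list alone, median -4.37, 1.29e-07, and adjusted p = 0.191 with an estimated correlation), T cell members in 10 of 13 (median -2.87, 0.000292, and adjusted p = 0.405 with an estimated correlation) and antigen presentation members in 10 of 14 (median -1.64, 0.000292, and adjusted p = 0.405 with an estimated correlation). Lymph node stroma fell in 4 of 6 (median -2.32, 0.000345, and adjusted p = 0.393 with an estimated correlation), and regulatory T cell and tolerance genes in 8 of 14 (median -1.51, 0.000292, and adjusted p = 0.393 with an estimated correlation). Skeletal muscle transcripts were also lower, with a median of -5.29 and 2 of 11 members past the threshold (0.0085, and adjusted p = 0.561 with an estimated correlation). In all, 1628 genes rose and 1669 fell, 1309 and 1320 of them at least 2-fold, and the values of 3261 did not overlap between groups. With no filter on dim probes 1740 rose and 1434 fell, so which direction was larger depended on the processing. Values did not overlap in 47.5% of all genes, where chance gives 10%. The count was 2110 without untreated replicate 2, and 1864, 1918 and 2114 without AHC replicates 1, 2 and 3. The 3 AHC arrays were close to each other (median SD 0.184), and with them averaged to 1 sample, as were the untreated arrays of week 30, 3 genes were called. That fit has 1 sample in the AHC arm and takes its spread from the other, more variable groups.

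**Figure D3:**
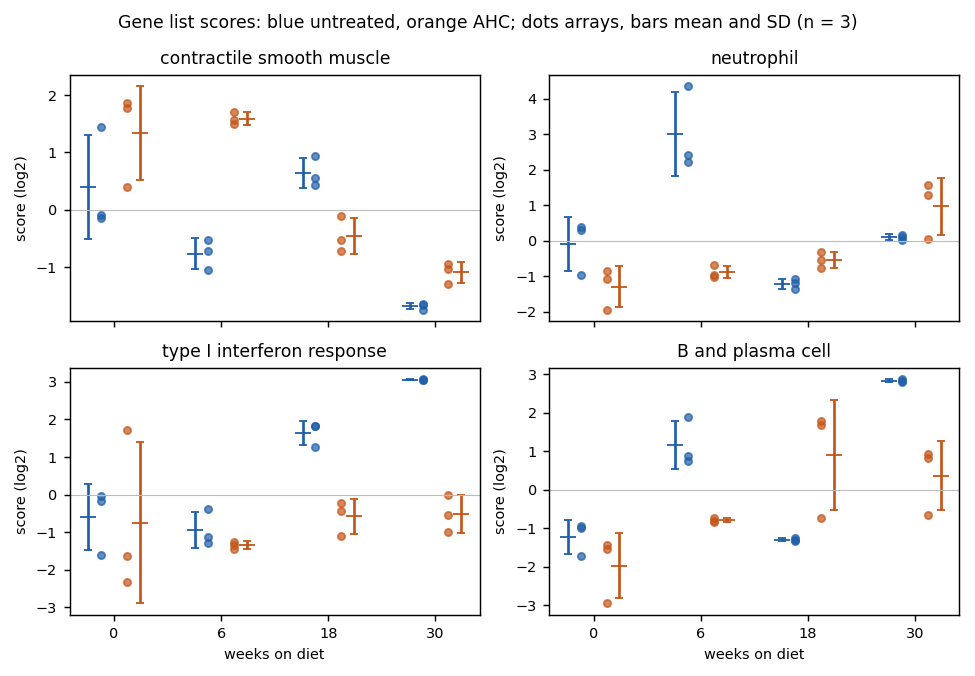
Scores of 4 gene lists (vertical, log2) by week on the diet (horizontal) for untreated (blue) and AHC (orange) arrays, with mean and SD of n = 3. The smooth muscle score was 1.59 with AHC and -0.76 untreated at week 6, and the interferon score 3.05 untreated and -0.51 with AHC at week 30.

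At week 18, lymphocyte transcripts were higher with AHC, unlike at week 6. H2-Ob, which tunes antigen loading in B cells, rose by 4.13 ± 0.81 (adjusted p = 0.00543) and the chemokine receptor Ccr6 by 3.48 ± 0.65 (0.00394). Foxp3, the master regulator of regulatory T cells, rose by 1.76 ± 0.31 (0.00313), and Pdcd1, Icos and Tnfrsf4, receptors on activated or regulatory T cells, by 3.32 ± 0.61 (0.00381), 3.09 ± 0.65 (0.00749) and 2.49 ± 0.49 (0.00493). Il10 measured 1.08 ± 0.44 (0.104). Ccl19 and Madcam1 of lymphoid stroma rose by 2.13 ± 0.40 (0.00416) and 2.15 ± 0.39 (0.00328). The largest rises were of major urinary protein genes, which are known from liver: Mup18 by 8.26 ± 1.18 (0.000768) and Mup19 by 7.69 ± 0.96 (0.000331). The interferon-induced Ifit3 fell by 3.94 ± 0.71 (0.00328).

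The B and plasma cell list at week 18 rose in 7 of 12 members (8 adjusted over the list alone, median 2.49, camera adjusted p = 9.53e-08, and adjusted p = 0.298 with an estimated correlation). T cell members rose in 5 of 13 (9 adjusted over the list alone, median 2.02, 9.53e-08, and adjusted p = 0.31 with an estimated correlation), and regulatory T cell and tolerance members in 5 of 14 (10 adjusted over the list alone, median 1.20, 1.02e-07, and adjusted p = 0.298 with an estimated correlation). Lymph node stroma, a tissue marker, rose in 4 of 6 (median 2.14, 2.43e-05, and adjusted p = 0.298 with an estimated correlation); its score ran from -0.58 to 1.99 over the AHC arrays. Interferon response members fell in 6 of 13 (8 adjusted over the list alone, median -2.48, 0.000187, and adjusted p = 0.584 with an estimated correlation). Contractile smooth muscle had 1 of 12 members past the threshold, lower (median -0.97, camera adjusted p = 0.0369, and adjusted p = 0.584 with an estimated correlation), a call that ended without untreated replicate 1 (-0.81) or AHC replicates 1 (-0.77) or 3 (-0.81). Cardiomyocyte transcripts fell in 4 of 13 (median -5.34, 0.00154, and adjusted p = 0.584 with an estimated correlation) and lung transcripts in 2 of 9 (median -5.01, 0.00774, and adjusted p = 0.584 with an estimated correlation). In all, 452 genes rose and 1532 fell, and values did not overlap in 37.8% of all genes, where chance gives 10%. The median of all genes was -0.209, and -0.092 after normexp. The count was 472 and 585 without untreated replicates 2 and 3, 486 without AHC replicate 1 and 3467 without AHC replicate 2. A fit on only the arrays compared called 1280.

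At week 30, interferon, lymphocyte and cell cycle transcripts were lower with AHC, and transcripts of muscle, mitochondria and cholesterol synthesis higher. Irf7, which drives interferon transcription, fell by 4.58 ± 0.70 (adjusted p = 0.000152), Isg15 by 4.37 ± 0.68 (0.000166), Oas2 by 4.31 ± 0.42 (5.17e-06) and the chemokine Cxcl10 by 4.48 ± 1.01 (0.00214). Cd3e of T cells fell by 1.90 ± 0.41 (0.00167), the peptide transporter Tap1 by 3.02 ± 0.49 (0.000233) and the replication genes Mcm2 and Pcna by 2.76 ± 0.57 (0.00126) and 1.57 ± 0.27 (0.000326). Sct, which encodes secretin, fell by 6.62 ± 0.74 (1.58e-05). Of cholesterol synthesis, Fdps rose by 1.34 ± 0.25 (0.000574) and Sc5d by 1.52 ± 0.29 (0.000693). Tissue transcripts were among the largest rises: Sln and Myh8 of muscle by 9.56 ± 2.70 (0.00881) and 8.84 ± 2.21 (0.00424), Mup19 by 8.21 ± 0.96 (2.07e-05), and the pancreatic genes Sycn and Cela1 by 7.74 ± 1.58 (0.00112) and 7.60 ± 1.56 (0.00113). Wt1 of mesothelium rose by 2.98 ± 0.51 (0.000333). The pancreatic rise was uneven: Sycn was -1.34, 8.59 and 8.35 on AHC replicates 1, 2 and 3, and Cela1 -2.81, 6.92 and 7.31. Hspd1, which encodes the heat shock protein 60 of the vaccine, rose by 0.94 ± 0.35 (0.0349). Its call ended without untreated replicates 1 (0.90), 2 (0.95) or 3 (0.96) and without AHC replicates 1 (0.79) or 3 (0.93). At weeks 0, 6 and 18 the mean of Hspd1 was lower with AHC, with values that overlapped between the arms. It was 5.12, 4.21 and 4.91 with AHC, against 5.29, 4.77 and 5.51 untreated.

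Interferon response members fell in 12 of 13 at week 30 (13 adjusted over the list alone, median -3.70, camera adjusted p = 3.87e-06, and adjusted p = 0.545 with an estimated correlation), and cell cycle members in 16 of 16 (median -2.75, 5.68e-06, and adjusted p = 0.545 with an estimated correlation). B and plasma cell members fell in 8 of 12 (9 adjusted over the list alone, median -2.85, 0.000785, and adjusted p = 0.545 with an estimated correlation), T cell members in 9 of 13 (10 adjusted over the list alone, median -2.42, 0.0043, and adjusted p = 0.545 with an estimated correlation) and antigen presentation members in 12 of 14 (median -1.91, 0.000454, and adjusted p = 0.545 with an estimated correlation). Oxidative phosphorylation rose in 15 of 16 (median 1.51, 0.000454, and adjusted p = 0.622 with an estimated correlation) and cholesterol synthesis in 11 of 17 (median 1.04, 0.00381, and adjusted p = 0.545 with an estimated correlation). Skeletal muscle rose in 7 of 11 (median 6.39, 0.00488, and adjusted p = 0.658 with an estimated correlation), brown fat in 9 of 10 (median 2.31, 0.00243, and adjusted p = 0.545 with an estimated correlation) and mesothelium in 7 of 7 (median 3.55, 0.000602, and adjusted p = 0.545 with an estimated correlation). In all, 3764 genes rose and 3851 fell, 3326 and 2682 of them at least 2-fold. With no filter on dim probes 3981 rose and 3659 fell, so which direction was larger depended on the processing. Values did not overlap in 63.6% of all genes, where chance gives 10%. The 3 untreated arrays were nearly identical (median SD 0.106), so the pooled variance of the fit was above their own. With them averaged to 1 sample, as were the AHC arrays of week 6, 668 genes were called, with the spread taken from the other, more variable groups.

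**Figure D4:**
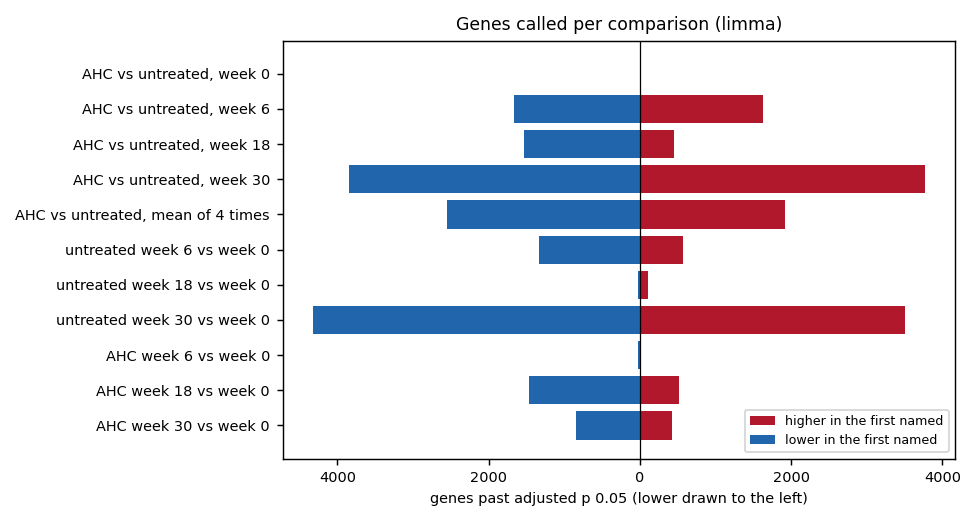
Number of genes called by limma (horizontal, higher to the right and lower to the left) in each comparison (vertical). AHC against untreated gave 1, 3297, 1984 and 7615 genes at weeks 0, 6, 18 and 30.

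Averaged over the 4 weeks, smooth muscle and matrix transcripts were higher with AHC and interferon transcripts lower. Itih4, a plasma protease inhibitor, rose by 2.44 ± 0.42 (adjusted p = 0.00208, n = 12 per arm), Pde5a, which breaks down cyclic GMP in smooth muscle, by 2.22 ± 0.34 (0.00134), and the elastic fibre gene Mfap4 by 2.14 ± 0.43 (0.0037). Lmod1 rose by 1.02 ± 0.23 (0.00628), Acta2, the smooth muscle actin, by 0.91 ± 0.26 (0.0185) and Mgp, an inhibitor of calcification, by 0.79 ± 0.20 (0.00993). Ifit3 fell by 2.13 ± 0.36 (0.00208), Usp18 by 1.77 ± 0.36 (0.00385), Oasl2 by 1.70 ± 0.31 (0.00245) and the chemokine Ccl8 by 1.78 ± 0.36 (0.0038). Interferon response members fell in 13 of 13 (median -1.57, camera adjusted p = 2.34e-06, and adjusted p = 0.792 with an estimated correlation), and antigen presentation members in 10 of 14 (median -0.82, 0.00285, and adjusted p = 0.792 with an estimated correlation). Smooth muscle members rose in 9 of 12 (median 0.90, 0.000203, and adjusted p = 0.792 with an estimated correlation) and matrix members in 5 of 18 (median 0.73, 0.00021, and adjusted p = 0.792 with an estimated correlation). In all, 1924 genes rose and 2554 fell, but 3490 rose and 2544 fell with no filter on dim probes. For smooth muscle, matrix and antigen presentation this average combines opposite signs. At week 18 the smooth muscle score was -0.45 with AHC and 0.65 untreated, and the matrix score -0.50 and 0.11. Antigen presentation was lower with AHC at weeks 6 and 30. At week 18 its list median was 0.36 in the fit without AHC replicate 3, where its call ended. The fit of all arrays called 4478 genes for the mean in limma (6947 at unadjusted p < 0.05). These calls did not hold with the close arrays of AHC week 6 and untreated week 30 averaged to 1 sample each. That fit takes its spread from the more variable groups.

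In untreated aortas, neutrophil and B cell transcripts were higher at week 6 than at week 0. S100a8 and S100a9 rose by 3.88 ± 0.67 (adjusted p = 0.00463) and 3.59 ± 0.61 (0.00461), and Derl3, of the secretory pathway of plasma cells, by 3.84 ± 0.88 (0.0164). Ccl19 rose by 2.28 ± 0.40 (0.00513) and the peptide transporter Tap2 by 1.65 ± 0.28 (0.00461). Lmod1 fell by 2.13 ± 0.46 (0.0134), Jun by 2.07 ± 0.25 (0.000599), the clock-controlled Tef by 1.65 ± 0.32 (0.00785) and Hbb-b1, a haemoglobin chain, by 3.72 ± 0.80 (0.0127). Neutrophil members rose in 7 of 10 (median 3.42, camera adjusted p = 5.45e-09, and adjusted p = 0.182 with an estimated correlation), B and plasma cell members in 5 of 12 (11 adjusted over the list alone, median 1.98, 7.79e-08, and adjusted p = 0.29 with an estimated correlation) and T cell members in 4 of 13 (11 adjusted over the list alone, median 2.57, 4.25e-07, and adjusted p = 0.29 with an estimated correlation). The tissue marker list of lymph node stroma rose in 4 of 6 (median 2.35, 2.28e-05, and adjusted p = 0.29 with an estimated correlation). Lists of skeletal muscle, lung and Schwann cells were called too, and each call ended without week 0 replicate 3 (medians 0.11, -0.31 and 0.10). The skeletal muscle score was -0.06 at week 0 and 2.15 at week 6, and lung ran from -1.70 to 5.41 over the week 6 arrays. Immediate early genes fell in 7 of 14 (median -1.05, 0.000365, and adjusted p = 0.29 with an estimated correlation). In all, 574 genes rose and 1328 fell, and values did not overlap in 26.6% of all genes, where chance gives 10%. The count was 422, 629 and 4054 without week 0 replicates 1, 2 and 3, and 422 and 835 without week 6 replicates 1 and 2. A fit on only the arrays compared called 0 genes in limma, against 1902 called in the fit of all arrays (5118 at unadjusted p < 0.05).

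By week 18, 131 genes differed from week 0 in untreated aortas. Adsl, an enzyme of purine synthesis, rose by 2.04 ± 0.29 (adjusted p = 0.00557), and Tmem242, an assembly factor of the mitochondrial ATP synthase, by 2.15 ± 0.33 (0.00685; not called without week 18 replicate 3, 2.01). Ifit2, induced by interferon, rose by 2.70 ± 0.58 (0.0341); its call ended without week 0 replicates 1 (2.93) or 2 (3.02) and without week 18 replicates 1 (2.93), 2 (2.50) or 3 (2.68). Interferon response members rose in 2 of 13 (11 adjusted over the list alone, median 2.52, camera adjusted p = 5.58e-08, and adjusted p = 0.919 with an estimated correlation). The neutrophil list had a median of -1.49 (0.00828, and adjusted p = 0.919 with an estimated correlation), with 4 of 10 members lower when adjusted over the list alone. Lists of another tissue and of metabolism were also called higher, but each call ended when 1 array was left out. Skeletal muscle had a median of 4.78 (0.000196, and adjusted p = 0.919 with an estimated correlation) and cholesterol synthesis 0.35 (0.0208, and adjusted p = 0.919 with an estimated correlation), neither called without week 0 replicate 3 (1.99 and 0.37). Oxidative phosphorylation had a median of 0.44 (0.043, and adjusted p = 0.919 with an estimated correlation), not called without week 0 replicate 3 (-0.07) or week 18 replicates 2 (0.42) or 3 (0.36). In all, 107 genes rose and 24 fell, a share of 81.7% rising that became 66.6% after normexp and 49.4% with no filter on dim probes (114 rose and 117 fell). Time and slide are largely tied here, and with the slide as a block 721 genes were called. Values did not overlap in 30.4% of all genes, where chance gives 10%. The count was 60, 24 and 817 without week 0 replicates 1, 2 and 3, and 29, 10 and 4 without week 18 replicates 1, 2 and 3. A fit on only the arrays compared called 0 genes in limma, against 131 called in the fit of all arrays (3218 at unadjusted p < 0.05).

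By week 30, untreated aortas had the highest lymphocyte and interferon transcripts of the study. Derl3 rose over week 0 by 6.84 ± 0.88 (adjusted p = 1.9e-05), Mzb1 of plasma cells by 6.27 ± 0.89 (4.71e-05) and Zap70, the T cell receptor kinase, by 4.12 ± 0.78 (0.000456). Cxcl10 and Ifit2 rose by 5.25 ± 1.01 (0.000518) and 3.59 ± 0.58 (0.000123), and Ccl19 by 3.59 ± 0.40 (5.49e-06). Cnn1 and Tagln of smooth muscle fell by 2.88 ± 0.54 (0.000408) and 2.07 ± 0.40 (0.00054), Mgp by 2.28 ± 0.40 (0.000233) and the clock-controlled Dbp by 3.76 ± 0.53 (4.21e-05). Heart transcripts fell furthest, Nppa by 8.79 ± 2.10 (0.00271) and Tnnt2 by 8.46 ± 1.80 (0.00121), and Sftpd of lung was at least 74.8-fold lower (0.000669). B and plasma cell members rose in 12 of 12 (median 3.90, camera adjusted p = 8.91e-07, and adjusted p = 0.405 with an estimated correlation), interferon members in 13 of 13 (median 3.59, 8.91e-07, and adjusted p = 0.405 with an estimated correlation), cell cycle members in 16 of 16 (median 2.66, 1.08e-06, and adjusted p = 0.425 with an estimated correlation) and lymph node stroma in 5 of 6 (median 4.01, 0.000496, and adjusted p = 0.405 with an estimated correlation). Smooth muscle fell in 9 of 12 (median -2.03, 0.000478, and adjusted p = 0.425 with an estimated correlation) and cardiomyocyte transcripts in 9 of 13 (median -5.03, 0.00428, and adjusted p = 0.647 with an estimated correlation). In all, 3510 genes rose and 4317 fell. The balance depended on the processing: 3384 rose and 3124 fell after quantile normalization, 3512 and 3024 after normexp, and 3456 and 6698 with no filter on dim probes. Values did not overlap in 62% of all genes, where chance gives 10%. The median of all genes was -0.209, and -0.092 after quantile normalization and -0.09 after normexp, a shift far below the values printed. With the untreated week 30 arrays averaged to 1 sample, as were the AHC arrays of week 6, 1722 genes were called.

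In AHC aortas, Fos rose from week 0 to week 6 by 1.96 ± 0.19 (adjusted p = 9.91e-05), and Slc40a1, which exports iron from macrophages, fell by 2.27 ± 0.31 (0.00313). Slc25a33, a mitochondrial pyrimidine carrier, fell by 2.47 ± 0.37 (0.00639); its call ended without week 6 replicates 1 (-2.40) or 2 (-2.38). Dgat2 of triglyceride synthesis fell by 2.79 ± 0.49 (0.0203), a call that ended without week 0 replicate 1 (-2.41) or week 6 replicates 1 (-2.70), 2 (-2.79) or 3 (-2.89). Oxidative phosphorylation transcripts had a median of -1.55 with 0 of 16 members past the threshold and 16 lower when adjusted over the list alone (camera adjusted p = 5.58e-08, and adjusted p = 0.543 with an estimated correlation). Fatty acid oxidation had a median of -1.62 (6.92e-05, and adjusted p = 0.543 with an estimated correlation), with 11 of 15 lower when adjusted over the list alone. Fat transcripts were lower in the same comparison: adipocyte members had a median of -1.62 (0.000895, and adjusted p = 0.606 with an estimated correlation) and brown fat members -1.52 (0.0256, and adjusted p = 0.659 with an estimated correlation), the latter not called without week 0 replicate 1 (-0.97). In all, 4 genes rose and 26 fell, with 3171 at unadjusted p < 0.05. The median of all genes was -0.186, and -0.079 after normexp, where 12 genes rose and 15 fell. Values did not overlap in 37.1% of all genes, where chance gives 10%. The count was 14 without week 0 replicate 1, and 5, 6 and 7 without week 6 replicates 1, 2 and 3. It was 306 with the slide as a block, 1 in a fit on only the arrays compared, and 0 with the week 6 arrays averaged to 1 sample, as were the untreated arrays of week 30.

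By week 18, lymphocyte transcripts were higher and smooth muscle transcripts lower than at week 0 in AHC aortas. Cd79b of the B cell receptor rose by 4.08 ± 0.84 (adjusted p = 0.00618), Gimap3 of lymphocyte survival by 3.72 ± 0.75 (0.00584) and Ccl19 by 2.10 ± 0.40 (0.00453). Foxp3 rose by 1.70 ± 0.31 (0.00395), from week 0 arrays of which 1 of 3 was above background. Mup19 rose by 5.64 ± 0.96 (0.00274). Dsp of desmosomes fell by 3.68 ± 0.64 (0.00327), the clock gene Per2 by 2.73 ± 0.45 (0.00243) and Jun by 1.49 ± 0.25 (0.00255). T cell members rose in 10 of 13 (median 3.50, camera adjusted p = 1.7e-11, and adjusted p = 0.146 with an estimated correlation), B and plasma cell members in 8 of 12 (10 adjusted over the list alone, median 2.53, 1.58e-10, and adjusted p = 0.146 with an estimated correlation) and regulatory T cell and tolerance members in 8 of 14 (11 adjusted over the list alone, median 1.60, 1.35e-08, and adjusted p = 0.146 with an estimated correlation). Lymph node stroma rose in 5 of 6 (median 2.26, 1.89e-06, and adjusted p = 0.146 with an estimated correlation). Smooth muscle members fell in 11 of 12 (median -1.84, 4.14e-06, and adjusted p = 0.221 with an estimated correlation). In all, 520 genes rose and 1471 fell; the median of all genes was -0.164, and -0.045 after normexp. Values did not overlap in 21.1% of all genes, where chance gives 10%. The count was 451 and 1131 without week 0 replicates 2 and 3, and 546, 3463 and 890 without week 18 replicates 1, 2 and 3. A fit on only the arrays compared called 0 genes in limma, against 1991 called in the fit of all arrays (4393 at unadjusted p < 0.05). Another split of the same 6 arrays gave 2033 genes.

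By week 30, smooth muscle transcripts of AHC aortas were lower than at week 0, while neutrophil and cholesterol synthesis transcripts were higher. Tagln fell by 2.62 ± 0.40 (adjusted p = 0.00206), Myl9 by 2.39 ± 0.40 (0.00319), Cnn1 by 3.01 ± 0.54 (0.00444), Dmd by 3.27 ± 0.58 (0.00414) and the matrix gene Optc by 4.66 ± 0.75 (0.00282). S100a9 and S100a8 rose by 3.78 ± 0.61 (0.00285) and 3.74 ± 0.67 (0.00444), and Mup19 by 5.10 ± 0.96 (0.00631). The sterol enzymes Mvd and Sc5d rose by 2.18 ± 0.36 (0.0031) and 2.03 ± 0.29 (0.0016). Smooth muscle members fell in 11 of 12 (median -2.75, camera adjusted p = 3e-11, and adjusted p = 0.197 with an estimated correlation) and matrix members in 6 of 18 (14 adjusted over the list alone, median -1.69, 4.2e-07, and adjusted p = 0.314 with an estimated correlation). T cell members rose in 8 of 13 (10 adjusted over the list alone, median 3.00, 2.75e-07, and adjusted p = 0.233 with an estimated correlation), neutrophil members in 5 of 10 (median 2.43, 1.76e-06, and adjusted p = 0.204 with an estimated correlation) and cholesterol synthesis members in 6 of 17 (9 adjusted over the list alone, median 1.06, 3.77e-08, and adjusted p = 0.0886 with an estimated correlation). Lymph node stroma rose in 3 of 6 (median 2.09, 5.11e-05, and adjusted p = 0.228 with an estimated correlation). Fat and skeletal muscle lists were called higher too. The adipocyte list (median 0.87, 0.0107, and adjusted p = 0.586 with an estimated correlation) lost its call without week 0 replicate 3 (0.44) or week 30 replicate 1 (0.43), and so did brown fat (median 0.72, 0.0371, and adjusted p = 0.621 with an estimated correlation), at 0.08 and 0.39. Skeletal muscle (median 3.77, 0.0177, and adjusted p = 0.621 with an estimated correlation) lost it without week 0 replicates 2 (2.47) or 3 (1.80) or week 30 replicates 2 (3.22) or 3 (3.09). In all, 423 genes rose and 843 fell, and values did not overlap in 18.5% of all genes, where chance gives 10%. The count was 2728, 165 and 475 without week 0 replicates 1, 2 and 3, and 2012, 364 and 605 without week 30 replicates 1, 2 and 3. It was 195 without replicates 2 and 3 together, which carried pancreatic transcripts. A fit on only the arrays compared called 0 genes in limma, against 1266 called in the fit of all arrays (3835 at unadjusted p < 0.05). Another split of the same 6 arrays gave 1653 genes.

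The difference between AHC and untreated changed with time in 7342 genes by the F test of limma. Fos had the largest F, 82.2 (adjusted p = 1.03e-06), with differences of 0.05, 3.17, -0.68 and -0.30 at weeks 0, 6, 18 and 30. Sgca, a sarcoglycan of muscle membranes, followed with F 60.8 (4.99e-06) and differences of 0.72, 1.18, -2.20 and 3.64, and Sync, which binds desmin filaments, had F 49.8 (9.7e-06) and 0.92, 4.04, -1.41 and 1.31. Against week 0, the difference changed in 16 genes at week 6, 1007 at week 18 and 3112 at week 30. Immediate early genes rose in 3 of 14 at week 6 relative to week 0 (median 1.50, camera adjusted p = 1.85e-11, and adjusted p = 0.0488 with an estimated correlation). At week 18 T cell members rose in 6 of 13 (12 adjusted over the list alone, median 4.09, 2.04e-09, and adjusted p = 0.156 with an estimated correlation). At week 30 interferon members fell in 8 of 13 (10 adjusted over the list alone, median -3.37, 1.3e-05, and adjusted p = 0.693 with an estimated correlation) and mesothelium members rose in 6 of 7 (median 4.05, 0.000108, and adjusted p = 0.693 with an estimated correlation).

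Changes over time were compared between the arms across genes, which are not independent replicates. From week 0 to week 30 the Pearson r of untreated and AHC changes was 0.27 (Spearman 0.21) across genes, and 0.39 with the slide as a block; 249 genes rose in both arms, where 88.6 were expected, 543 fell in both, where 217 were expected, and 68 went opposite ways. Of the genes above, Cnn1 and Tagln fell and Ccl19 rose in both arms. At week 18 r was 0.01 across genes, and 0.40 with the slide as a block, and 16 genes went opposite ways. At that week 3 genes rose in both, where 3.32 were expected, and 2 fell in both, where 2.11 were expected. At week 6 r was 0.36 across genes, with 4 genes falling in both where 2.06 were expected, and too few calls in AHC aortas to count rises. Both changes share the trend of age and diet, but are counted from separate week 0 groups. With the slide as a block, both arms at weeks 18 and 30 also subtract the same estimated slide difference. Its error enters both changes and can raise r by itself, so these higher values cannot be read as shared change. At week 6, on the slides of week 0, r stayed at 0.36 with the block. Treatment differences of weeks 18 and 30 had r = -0.27 across genes, and those of weeks 0 and 6 r = 0.56.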

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

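The tests on sex-linked transcripts and on sex or strain at week 30 were chosen after the result was seen; the splits of the arrays, the test on pancreatic arrays and the test on tissue scores were set before their result was seen.

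The difference between AHC and untreated aortas changed with time in 7342 genes by the F test, and against week 0 it changed in 16 genes at week 6, 1007 at week 18 and 3112 at week 30. What drew attention here was the tested difference between time points. Fos is the clearest gene, at 0.05 at week 0 and 3.17 at week 6.

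Of 100 splits of the arrays within the weeks, 1, the real one, gave as many genes for the interaction (7342 against 4283 for the next). For the mean of the 4 weeks it was also 1 (4478 against 2865). Only if every array is a separate sample does this exclude a chance split, and then for a difference between the arms at any week. Because the splits remove the treatment difference at every week, they cannot test its change with time by itself. The real split also follows Ddx3y at weeks 18 and 30. The splits also break up the close arrays of untreated week 30 and AHC week 6, and with these averaged to 1 sample each, and the spread taken from the more variable groups, the counts were 850 for the interaction and 0 for the mean. With 3 against 3 arrays there are 10 splits, too few for a share under 0.05. The real counts and the highest of the other splits were 3297 and 1 at week 6, 1984 and 2 at week 18, and 7615 and 1 at week 30, where 1 split, the real one, gave as many genes. In the untreated arm they were 1902 and 509 at week 6, 131 and 2 at week 18, and 7827 and 0 at week 30, and for AHC at week 6 they were 30 and 1, again with 1 split as large. At week 0, 4 of the 10 splits gave at least the real count of 1, and the split of untreated replicates 1 and 2 with AHC replicate 1 against the rest gave 5679. That split follows Ddx3y and points to a structure of the samples other than treatment. For AHC at weeks 18 and 30 against week 0, 2 splits were as large as the real one (1991 against 2033, and 1266 against 1653); each set AHC week 0 replicate 1, the array with Ddx3y, with 2 later arrays.

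On 13 arrays labelled male, Xist was above background and Ddx3y was not. A failure of the Ddx3y probe alone is argued against by Eif2s3y, which has its own probe: on 0 of the 13 arrays did it reach its range on the arrays with Ddx3y (1.45 to 2.99). RNA of both sexes mixed on an array is argued against on 11 of the 13, where neither Ddx3y nor Eif2s3y was above background. The other 2, AHC week 18 replicate 2 and AHC week 30 replicate 1, had Eif2s3y (-1.31 and -0.35). Eif2s3y alone does not tell mixing from other causes. Their Ddx3y was -6.42 and -5.75, not above background. Where Ddx3y was above background it ran from 0.26 to 2.40, near Eif2s3y. These values argue against mixing on the 2 arrays too, and the source of their Eif2s3y signal stays open. Outside the 13, mixing was not tested and stays open on the 2 arrays with both Xist and Ddx3y above background. These were untreated week 0 replicate 1 (Xist -2.42) and untreated week 18 replicate 1 (Xist -2.95). A second Xist probe was above background on the latter (-3.93) but not on the former (-5.94). A swap of single arrays between treated and untreated groups at weeks 6, 18 and 30 would need treated arrays with Ddx3y, and 0 were found. That count was known before this test was chosen. It cannot speak to treated and untreated groups exchanged as a whole at week 18 or 30, which would also leave it at 0. At week 0 the 2 arrays that differ from their groups, AHC replicate 1 and untreated replicate 3, cannot be told apart from a swapped pair, and animals of another sex than the label, or single wrong labels, stay open for all 13.

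The week 30 difference of 7615 genes was not wholly due to the pancreatic transcripts of AHC replicates 2 and 3, since 5113 genes were called without these 2 arrays, with the 1 array left assumed to vary like the other groups. With the scores of heart muscle, skeletal muscle, lung and B cell transcripts as covariates 334 genes were called. The scores differ with treatment, so tissue composition and treatment cannot be told apart by this test. Sex or strain cannot be told apart from treatment either, as 0 arrays of week 30 had the Ddx3y state of the other treatment. An effect of AHC is the biological explanation the design names, and it stays open.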

How the results depend on the processing

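The alternatives that left out groups of arrays, averaged arrays, used tissue scores, used all features or stayed within a slide were chosen after the data were seen; the others were set before. Of 305 counts recomputed, 186 kept within 1.5-fold of the value in the report and 119 did not. Of 3697 list results, 3205 kept direction and side of the threshold, 489 lost the call and 3 reversed in the direction of the test. Some that lost the call also had a median of the other sign, with the values in the last paragraph. Of 17108 gene values none past the threshold reversed, 14707 were the same, 1754 lost the call and 647 gained it. A change of sign between values past the threshold in neither fit was counted as the same. Results with 3 arrays a group rest on a spread that differed between groups (0.106 to 0.529, log2), and between 43% and 71.7% of spots were well above background. The causes of the changes below were not tested, except where fewer arrays or more features were fitted.

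With AHC against untreated written as treatment, the count for treatment at week 0 was 0 with normexp, with quantile normalization, with the replicate block, with only the arrays compared, without the 11 arrays with Ddx3y, with the arrays of HFD week 30 and AHC week 6 averaged, without the 2 pancreatic arrays, and with all features. Untreated week 18 against week 0 gave 293 genes with normexp, 231 with no filter on dim probes, 211 with the mean of probes and 721 with the slide block. AHC week 6 against week 0 gave 102 with quantile normalization and 306 with the slide block, and AHC week 30 against week 0 gave 2626 with no filter. With the slide block the correlation of the arms across genes was 0.40 at week 18 and 0.39 at week 30. There both arms subtract the same estimated slide difference, whose error can raise the correlation by itself. With all features, treatment at week 30 gave 12412 and the mean of 4 weeks 7822.

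Array weights ran from 0.0974 to 7.96, did not converge, and gave 7263, 10231 and 12785 genes for treatment at weeks 0, 6 and 18, 11531 for the mean of 4 weeks, 8231 and 5193 for untreated weeks 6 and 18 against week 0, 6106, 10012 and 5214 for AHC weeks 6, 18 and 30 against week 0, and 14372 for the interaction. With only the arrays compared, treatment at week 18 gave 1280, untreated weeks 6 and 18 against week 0 gave 0 and 0, and AHC weeks 6, 18 and 30 against week 0 gave 1, 0 and 0. Within slide 1, treatment at week 0 gave 495, untreated week 6 against week 0 gave 4006 and AHC week 6 against week 0 gave 481. Within slide 2, treatment gave 116 at week 18 and 4860 at week 30.

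In this paragraph several arms hold 1 array or 1 averaged sample, which is assumed to vary like the other groups. Without the 13 arrays with Xist and no Ddx3y, 1 AHC array of week 0 is left; treatment at week 0 gave 2172, and untreated weeks 6 and 18 against week 0 gave 9357 and 6247. Without the 11 arrays with Ddx3y, 1 untreated array is left at each of weeks 0 and 6; treatment at week 6 gave 643, untreated week 6 against week 0 gave 127 and AHC week 6 against week 0 gave 9. Without the 3 arrays apart in sex-linked genes, treatment at weeks 0 and 18 gave 4940 and 4628, the mean 7609, untreated weeks 6 and 18 against week 0 gave 4357 and 1535, and AHC weeks 6, 18 and 30 against week 0 gave 350, 3508 and 4249. With the arrays of HFD week 30 and AHC week 6 averaged, treatment at weeks 6, 18 and 30 gave 3, 542 and 668, the mean 0, untreated weeks 6, 18 and 30 against week 0 gave 153, 3 and 1722, AHC weeks 6, 18 and 30 against week 0 gave 0, 648 and 200, and the interaction 850. Without the 2 pancreatic arrays, untreated week 18 against week 0 gave 238, and AHC weeks 6 and 30 against week 0 gave 74 and 195. With tissue scores as covariates, treatment at weeks 0, 6, 18 and 30 gave 19, 570, 581 and 334, the mean 251, untreated weeks 6, 18 and 30 against week 0 gave 210, 895 and 380, AHC weeks 6 and 18 against week 0 gave 808 and 355, and the interaction 3583.

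Leaving out 1 array at a time, treatment ran from 0 to 1473 at week 0, 1864 to 2969 at week 6, 472 to 3467 at week 18, 5747 to 7312 at week 30 and 3075 to 6678 for the mean. Untreated weeks 6, 18 and 30 against week 0 ran from 422 to 4054, 4 to 817 and 6024 to 7614, AHC weeks 6, 18 and 30 against week 0 from 5 to 36, 451 to 3463 and 165 to 2728, and the interaction from 5654 to 8796. Over these fits the smooth muscle list of AHC week 6 against week 0 ran from -0.21 (without AHC week 0 replicate 1) to 0.67, and with array weights it reversed to -0.19. Oxidative phosphorylation in untreated week 18 against week 0 ran from -0.07 (without untreated week 0 replicate 3) to 0.78. Medians of the other sign, with the call lost, were -0.20 for antigen presentation and -0.02 for cell cycle in AHC week 6 against week 0 without AHC week 0 replicate 2. In untreated week 6 against week 0 they were -0.31 for lung without untreated week 0 replicate 3 and -0.02 for Schwann and nerve within slide 1.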

Other observations

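All tests and lists in this part were chosen after the data were seen.

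AHC week 30 replicates 2 and 3 carried transcripts of the exocrine pancreas. The score of 16 acinar genes was 9.13 and 8.99 on these arrays and at most 0.37 on the other 22, in log2 relative to the 24 arrays. The protease gene Cpa1 was -2.88, 8.75 and 8.30 on AHC replicates 1, 2 and 3, the lipase Pnlip -1.33, 7.99 and 7.87, and the amylase Amy2a5 0.85, 8.50 and 8.34. Of 8 adrenal cortex genes listed, 2 were tested. The steroid hydroxylase Cyp21a1 was -1.07, 6.67 and 6.35 on AHC replicates 1, 2 and 3, and the corticotropin receptor Mc2r -1.25, 0.82 and 0.98.

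Ifi202b, an interferon-inducible gene that differs between mouse strains, followed Ddx3y. It was above background on all 11 arrays with Ddx3y, from -0.47 to 4.02, and on 1 array without, AHC week 30 replicate 2, with -6.66 to -1.64 on the arrays without. At week 18 it was at least 90.4-fold lower with AHC than untreated (limma adjusted p = 0.00965), where 0 of 3 AHC arrays were above background. At week 30 it was 4.00 ± 0.02 (SD) untreated and above background on 1 of 3 AHC arrays, at -1.64. Its second probe was not above background on that array (-6.26).

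The untreated week 30 arrays differed from each other by an SD of 0.128 to 0.175 over 12983 bright spots and the AHC week 6 arrays by 0.139 to 0.217, against 0.057 to 0.103 for replicate spots within an array. In other groups the SD between arrays reached 0.738, but untreated week 18 replicates 2 and 3 (0.209) and untreated week 0 replicates 1 and 2 (0.217) lay within the range of AHC week 6. Treatment differences of replicate 3, on slide 3, had r = -0.01, 0.59, 0.71 and 0.77 with those of replicates 1 and 2 at weeks 0, 6, 18 and 30 across genes, which are not independent replicates. Deviations of each array from its group mean were also correlated with those of arrays in other groups. For 11 of the 24 arrays the highest such correlation was with an array of their own replicate number. With 3 replicate numbers some such matches arise by chance, and every replicate 3 lay on slide 3. At week 0, deviations of treated and untreated arrays of the same number from their group had r = 0.63, -0.29 and 0.66 for replicates 1, 2 and 3 across genes. These values followed Ddx3y, which replicate 1 had in both arms, replicate 3 in neither and replicate 2 only in the untreated arm. At weeks 6, 18 and 30 such r ran from 0 to 0.20. The labels do not say that the numbers pair arrays.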
